A study of Mus musculus with 8 samples.

How the data were processed

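Gene expression was measured on arrays in midbrain tissue of C57/Bl mice. Per the labels, each of the 8 samples was total RNA from midbrains punched out and pooled from 5 mice that weighed 22 to 24 g. Mice received water (Control, 4 samples) or rasagiline mesylate at 0.1 mg/kg in 0.1 ml of water (Rasagiline, 4 samples), by mouth for 14 days. The labels do not say whether the 4 samples of a group came from 4 separate pools of mice or from repeat arrays of 1 pool. If they were repeats, the p-values measure only technical spread.

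The deposited table held 1 intensity per probe and array, for 1185 probes and 8 arrays. Its values were whole numbers on a linear scale, with 1 value missing, 86 exact zeros and 55 values below 0. The array type, background correction, normalization and detection rule behind the intensities are not given in the sources used here, and the table carried no background or detection flags. Values below 0 occurred on 4 arrays (Control 2 and Rasagiline 2, 3 and 4) and on none of the other 4, and exact zeros on all 8. The number of arrays limits the precision, and no depth or counting interval applies to array intensities.

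Probes were identified only by codes (M, MA or V followed by a number). None of the 1185 codes matched a gene symbol, locus tag or gene identifier in the mouse RefSeq table of assembly GRCm38.p6. A further 16 codes coincided with gene synonyms in that table, for instance M33, which is no evidence of identity and was not used. Probes are therefore reported by code, with no gene or genome position. The 26 gene lists fixed beforehand, cell type markers among them, could not be matched to probes and were not tested.

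Arrays were to be used as deposited if their median log2 intensities lay within 0.1 of each other, over probes above 0 on all arrays. These medians spanned 0.82 over 1063 probes, so the intensities were quantile normalized on the linear scale. Values below 0 were then set to 0, a step added after the negative values were seen, and transformed as log2(intensity + 1837). The pseudocount of 1837 was the median over arrays of the 10th percentile of the intensities above 0. Because it is large against the dim probes, a difference on this scale understates the change of a dim probe. Probes above 0 in at least 4 samples, with at least 2 values in each group, were tested, which kept all 1185.

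Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment over all probes. The threshold was an adjusted p under 0.05, and intervals are 95% intervals of the fit. Measures with 1 value per array were compared by an exact two-sided permutation test of the group labels. With 4 arrays against 4 its smallest possible p is 0.0286. The test, the groups, the rules above and the rule for named probes were fixed before the data were examined. That rule took, where fewer than 5 probes passed, the 10 probes higher and the 10 probes lower with rasagiline that had the smallest p. As no code could be tied to a gene, only the first 2 of each 10 are given by code and the rest as ranges.

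The fit was tested on simulated data, drawn for 1184 probes from their measured means and within-group SDs in the comparison of rasagiline with water, with 200 probes changed, 20 times. The share of changed probes recovered was 26.9% at a log2 change of 0.5, 66.7% at 1, 88.1% at 1.5 and 94.5% at 2. Of the probes called, 3.98% were unchanged ones. The Benjamini-Hochberg cut is more lenient with 200 changed probes than with few, and the simulated noise was independent between probes. The shares therefore do not give the power to find a few changed probes in the measured data.

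The numbers in the sample titles were tested as a possible pairing. Deviations from the group means of arrays with the same number correlated between -0.084 and 0.081, against -0.17 to 0.22 for arrays with different numbers, so the numbers were not used to pair samples. Alternatives to the scaling, the pseudocount, the filter, the variance model, the samples used and the test were computed, and their effect is given in the closing section. Figures were drawn with matplotlib 3.10.9.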

Results

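Rasagiline is an irreversible inhibitor of monoamine oxidase B, an enzyme that breaks down dopamine, and is used in Parkinson's disease. The midbrain holds the dopamine neurons of the substantia nigra and ventral tegmental area. The comparison was between midbrain RNA of mice given rasagiline and that of mice given water, with 4 arrays in each group and 1185 probes on each array.

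The dim part of the probes was read at different levels on the 8 arrays, and the bright part at nearly the same level. The median deposited intensity ranged from 3555 on Control 1 to 6340 on Control 2, with a coefficient of variation of 19.7% over the 8 arrays. The 90th percentile ranged only from 15849 to 17136, with a coefficient of variation of 2.47%. The median was 5019 ± 1172 (SD, n = 4) in the water group and 4478 ± 690 (SD, n = 4) in the rasagiline group, a difference within the spread between arrays (exact permutation test, two-sided p = 0.40, adjusted p = 0.64 over 15 array measures). Between 1 and 28 probes per array stood at or below 0, with 17.0 ± 7.3 (SD, n = 4) in the water group and 18.3 ± 12.1 (SD, n = 4) in the rasagiline group (exact permutation test, p = 0.91, adjusted p = 0.91). With a smallest possible p of 0.0286, no single array measure could have passed the adjustment over 15.

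**Figure D1:**
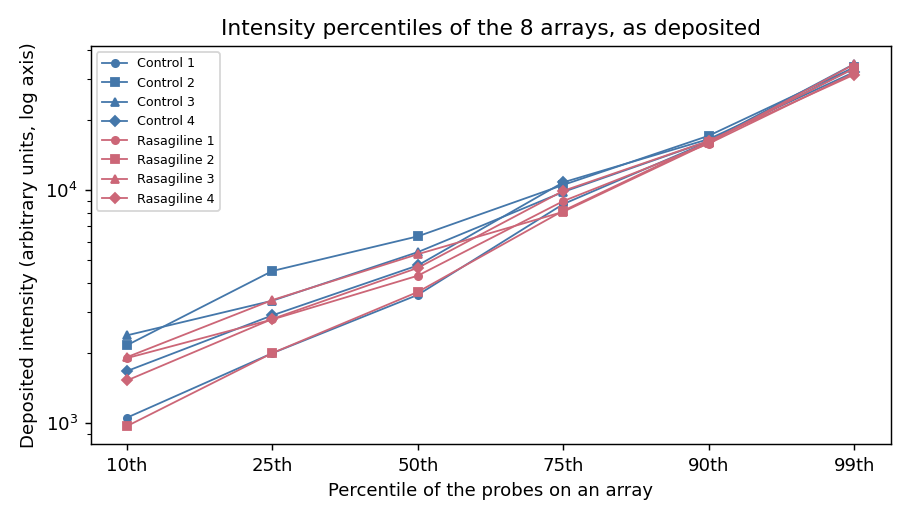
Deposited intensity (arbitrary units, log axis) at 6 percentiles of the probes on each array, with 1 line per array, water in blue and rasagiline in red. The lines are spread at the median, from 3555 to 6340, and meet at the 90th percentile, from 15849 to 17136.

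The correlation between arrays was of similar size within and between treatments. After quantile normalization, the correlation of log2 values across probes averaged 0.78 over the 6 pairs of water arrays, 0.73 over the 6 pairs of rasagiline arrays and 0.75 over the 16 pairs between groups. Probes on an array are not independent replicates, so these values describe the arrays only. The highest of the 28 correlations, 0.86, was between Control 1 and Rasagiline 2. The first principal component held 22.4% of the variance and did not separate the treatments (exact permutation test, p = 0.17). It set Rasagiline 3, at 16.5, apart from the other arrays, which lay between -5.8 and 2.7. Rasagiline 3 also had the lowest mean correlation with the other arrays, 0.69, against 0.74 to 0.78 for the rest.

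The spread between arrays of a group was large for all but the brightest probes. The median within-group SD of a probe was 0.34 on the log2 scale. It fell from 0.40 in the dimmest 25% of probes to 0.19 in the brightest 25%. The median 95% interval of a probe's difference between treatments extended 0.52 to either side on the log2(intensity + 1837) scale, and 0.36 in the brightest 25%. The median SD was 0.28 in the water group and 0.33 in the rasagiline group.

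Of the 1185 probes tested, 1 passed an adjusted p under 0.05 (limma, Benjamini-Hochberg). This was probe M567, which was higher with rasagiline. Its deposited intensity was 205 on Control 1 and was listed at 0 on Control 2, 3 and 4. It was 3595, 3249, 6257 and 5951 on Rasagiline 1 to 4, at percentiles from 40.2 to 62.6 of the probes on those arrays. On the log2(intensity + 1837) scale the difference was 1.78 (SE 0.17, 95% interval 1.39 to 2.16, limma adjusted p = 0.0038). The listed zeros entered the fit as 10.96 on Control 2 and 10.84 on Control 3 and 4. The spread of these values came from the normalization and the pseudocount. The SE, interval and p of M567 therefore rest in part on a spread that was not measured. The size of the difference depended on the pseudocount, with 2.90 for a pseudocount of 600.2 and 1.37 for one of 2912. No fold is given, because most of the water arrays were listed at 0. Exact zeros leaned towards dim probes but were not confined to them. At 71 other probes with 1 zero, the mean percentile of the remaining arrays of the group had a median of 40.4. This mean lay in the lowest 25% at 25 of the 71, and above the median at 27. M567 was not tested when values at or below 0 were taken as missing, when only probes above 0 on all arrays were kept or when the dimmest 25% of probes were left out, and no other probe passed then (85, 78 and 70 at an unadjusted p under 0.05).

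The next smallest adjusted p was 0.43, so no other probe passed. The probe with the second smallest p among those higher with rasagiline was MA185. It was listed at 0 on Control 1 and 2, at 2953 on Control 3 and at 1766 on Control 4, against 10802, 8662, 4452 and 6140 on Rasagiline 1 to 4. Its difference was 1.70 on the log2 scale (SE 0.35, limma adjusted p = 0.43). The 8 further probes on the higher side had differences from 0.46 to 1.32, with SEs from 0.12 to 0.38 and adjusted p of 0.59. In 6 of these 8 probes the 4 rasagiline arrays all lay above the 4 water arrays, which picking probes by a small p favours.

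On the lower side, probe M39 had a deposited intensity of 7898 ± 1113 (SD, n = 4) with water and 3794 ± 867 (SD, n = 4) with rasagiline. Its normalized difference was -0.63 on the log2 scale (SE 0.13, 95% interval -0.92 to -0.34, limma adjusted p = 0.43). Probe M33 stood at 5399 ± 2216 (SD, n = 4) with water and 2131 ± 137 (SD, n = 4) with rasagiline, a difference of -0.74 (SE 0.17, limma adjusted p = 0.59). In both probes every rasagiline array lay below every water array. The values of Rasagiline 3 were exactly 5000 for M39 and exactly 2000 for M33. The 8 further probes on the lower side had differences from -1.60 to -0.44, with adjusted p from 0.59 to 0.61. In 6 of these 8 probes the groups did not overlap. Picking by a small p favours this, for M39 and M33 too, so it is no separate support.

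**Figure D2:**
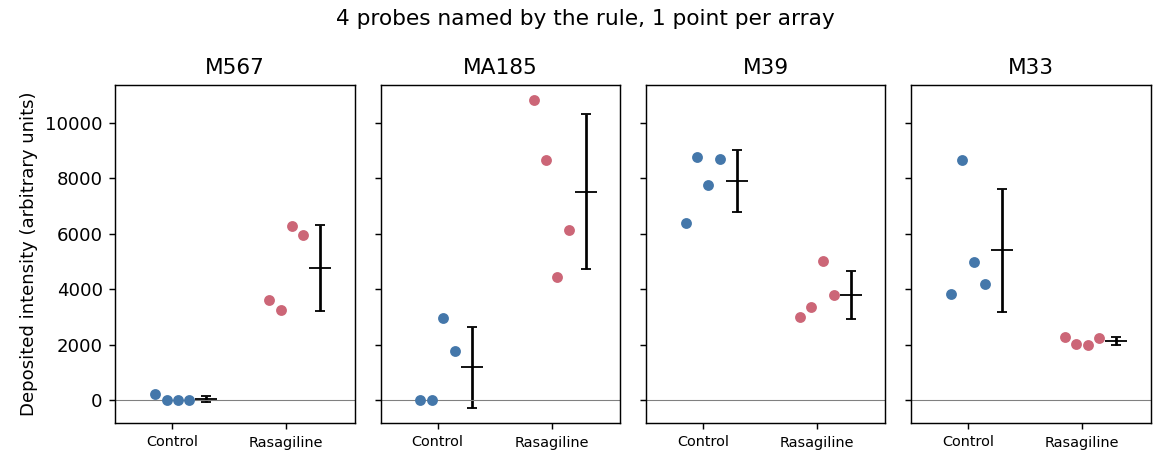
Deposited intensity (arbitrary units) of probes M567, MA185, M39 and M33, with 1 point per array, water in blue and rasagiline in red, and a black dash and bar for the mean and SD of the 4 arrays. The rasagiline arrays lie above the water arrays in M567 and MA185 and below them in M39 and M33, and only M567 passed the adjusted threshold.

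Quantile normalization places the centre of the differences near 0, so only their spread is informative. The median difference was 0.0026 on the log2 scale, and the middle of the distribution ran from -0.18 (25th percentile) to 0.18 (75th percentile). A difference of more than 1 in size was estimated for 17 probes, 9 higher and 8 lower with rasagiline. An unadjusted p under 0.05 was found for 79 probes, 40 higher and 39 lower, where 59.3 are expected by chance. Without Control 3 the count was 47, below that number, and over all arrays left out in turn it ranged up to 114, without Rasagiline 4. The groups did not overlap in 54 probes, or 4.56%, where chance gives 2.86% or 33.8 probes. Probes on an array are not independent, so how far this count strays by chance is not known.

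The balance between higher and lower probes depended on the scaling. With values as deposited, 62 probes had an unadjusted p under 0.05, of which 9 were higher and 53 lower with rasagiline, or 14.5% higher against 50.6% after quantile normalization. The median of all probes was then -0.11 on the log2 scale. M567 was the single probe past the adjusted threshold under both scalings.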

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

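The tests in this part were chosen after the result was seen, except the counts of other splits and the test on the other probes with a zero. In M567 the 205 of Control 1 stood apart from the other water arrays, all listed at 0. With the others tied at 0 any other value would have done so, and no chance rate applies.

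Probe M567 was at or near 0 on every water array and in the middle range of every rasagiline array. Zeros that fall independently on single arrays, and without regard to signal, would seldom do this. Shuffling the zeros over all probes within each array put 3 or more of a group on some probe in 0.64% of 10000 shuffles. The shuffle left aside that zeros leaned towards dim probes. It therefore cannot exclude independent zeros at a probe that was dim on the water arrays. A zero may however stand for a spot that was not measured, also at a probe with signal. At 71 other probes with 1 exact zero, the mean percentile of the remaining arrays of the group had a median of 40.4 (95% bootstrap interval 31.3 to 47.7). At 27 of these 71 probes this mean lay above the median, and at 25 in the lowest 25%. Zeros thus leaned towards dim probes but were not confined to them. Still open are, among others, chance, a spot unmeasured on several water arrays for a shared reason and a transcript raised by rasagiline. These data do not separate them.

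The number of calls could not be set apart from chance. Of the 35 splits of the 8 arrays into 4 and 4, 3, the treatments' own split included, gave as many probes past the adjusted threshold, where the treatments gave 1 and the highest other split 1. For an unadjusted p under 0.05, 5 of the 35 splits, again with the treatments' own, gave as many probes, where the treatments gave 79 and the highest other split 100.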

How the results depend on the processing

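Of the alternatives below, the offset, the block on negative values, both treatments of low or round values as missing and leaving out a pair of arrays were chosen after seeing the data. The 1 call, M567, fell to 0 calls when probes had to be above 0 in all samples (78 probes at an unadjusted p under 0.05), when the dimmest 25% were left out (70), when values at or below 0 were missing (85) and when zeros and multiples of 1000 were missing (78), since each of these left M567 untested. With the replicate block there were 0 calls (70 at an unadjusted p under 0.05) and M567 had an adjusted p of 0.20. An exact permutation test per probe gave 0 calls, with 54 at an unadjusted p under 0.05, M567 among them at its smallest possible p, 0.0286 (adjusted 0.63); it could not have called single probes and says nothing on M567. Thresholds of 0.1 and 0.25 gave 1 call. Leaving out each array in turn gave 1 to 2 calls, the second, a lower one, without Rasagiline 1, and 47 to 114 probes at an unadjusted p under 0.05, with 47 without Control 3 and 114 without Rasagiline 4, against 79. M567 passed in 19 of the 21 alternatives that tested it, with a difference from 1.37 (pseudocount at the 25th percentile) to 2.90 (at the 1st percentile) and an adjusted p from 0.0032 to 0.63. The 2 others were the block and the permutation test. The setting with no filter removed nothing and so repeated the main fit. All 21 alternatives kept the listed zeros of M567 as low values. Its passes therefore do not bear on whether these zeros were measured. With a block on whether an array held values below 0 the adjusted p of M567 was 0.043. Within the arrays that held such values (1 water, 3 rasagiline) the difference was 1.87, and within the others (3 water, 1 rasagiline) 1.53. MA185, M39 and M33 kept their direction and passed in none of the 24, 25 and 25 alternatives that tested them. The median within-group SD was 0.40 with values as deposited, against 0.34. Gene list tests and their alternatives were not run, because the probe codes are not tied to genes here. The median half-width of the intervals was 0.59 in the dimmest 25% of probes and 0.36 in the brightest 25%.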

Other observations

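The tests on round values and on code series were chosen after the result was seen. The probe codes fell into 3 series. The 597 probes of the M series had a median intensity of 4819, the 237 of the MA series 5554 and the 351 of the V series 3867. Their median differences between rasagiline and water were -0.0070, 0.0070 and 0.014 on the log2 scale, and no series passed a test against the others (camera with a preset correlation, adjusted p of 0.95 for all 3; unadjusted p from 0.65 to 0.95 with an estimated correlation). At an unadjusted p under 0.05, 23 of 42 probes of the M series, 4 of 15 of the MA series and 13 of 22 of the V series were higher with rasagiline.

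Whole multiples of 1000 were more frequent than expected. Of 9014 values of 1000 or more, 23 were such multiples against 9.01 expected (one-sided exact binomial p = 6.8e-05), whereas other multiples of 100 numbered 81 against 81.1. Numbers entered in place of low signals are a candidate source. Exactly 1000 or 2000 was listed for 12 of the 23, or 52.2%. Of the other values of 1000 or more, 17.3% lay from 1000 to under 2500, an odds ratio of 5.21 (Fisher's exact test, 95% interval 2.10 to 13.0). Values just under 1000 were left out of this comparison, which lowers the 17.3% and raises the odds ratio. Of the 23, 17 were on rasagiline arrays, 8 of them on Rasagiline 3, and 1 probe was listed at 1000 on 3 rasagiline arrays. The binomial test and the odds ratio take all values as independent. With such clustering the binomial p can be too small and the interval too narrow. Such multiples occurred in 5 of the 79 probes at an unadjusted p under 0.05, or 6.33%, against 1.45% of the others (Fisher's exact test, p = 0.010). M39 and M33, whose round values are given above, are among the 5. As the test was chosen after the result was seen, its p-value is descriptive only.

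Control 1 and Rasagiline 2, of different treatments, had the highest correlation of the 28 pairs of arrays. Spearman's rho across probes was 0.82 for this pair and 0.78 for the next. These arrays also had the lowest deposited medians, 3555 and 3659, and the lowest 10th percentiles, 1056 and 971. Their mean log2 correlations with all other arrays, this pair included, were the highest as well, at 0.779 and 0.777. Exchanged labels could not be decided: exchanging them gave 43 probes at an unadjusted p under 0.05 against 79, inside the range of 31 to 100 of all splits. The loss of the M567 call under the exchange (adjusted p = 0.85) had been set beforehand as evidence against it, but M567 was picked under the given labels, so this decides nothing. Without both arrays there were 68 probes at an unadjusted p under 0.05 and M567 still passed (limma adjusted p = 0.031). No biological explanation was tested.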
